A study of Mus musculus with 15 samples.

How the data were processed

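The study measured RNA of mouse E14 ES cells, unsorted, in libraries made from total RNA with the NEBNext Ultra Directional mRNA-seq kit, per the labels' protocols. Cells were nucleofected with 5 nmol of RC or LINE1 ASO, given 100 pmol of siRNA per well after 7 h and collected on day 2, per the labels. The 15 libraries are 3 replicates each of RC ASO with siControl, RC ASO with siDux, RC ASO with siNcl, LINE1 ASO with siControl and LINE1 ASO with siDux, and every column of the files was matched to one of them. The deposited values are counts of reads, in one table per gene (23284 genes and 92 ERCC spike-ins) and in another per repeat subfamily (1217 subfamilies). Per the submitters' processing notes, reads were trimmed with Trim Galore 0.4.0, aligned to mm9 with TopHat2 2.0.9 and tested with DESeq2 1.12.3 in R 3.3.0. How reads that map to several places were counted is not given in the sources used here, so changes of near-identical genes (Dux, Zscan4, Tcstv, Dub) and of repeats are uncertain. The reference at hand uses another genome build (GRCm38), so no coordinates are given.

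Gene counts per library came to 9.55 M to 27.6 M and ERCC counts to between 0.272% and 0.647% of them. ERCC rows were left out of library sizes and tests. The chi-square statistic per degree of freedom between replicates ran from 2.96 to 47.8, so no library is a copy of another. Deviations from the group means correlated between libraries of the same number by 0.186, 0.199 and 0.28 for the siDux comparison under RC ASO and by 0.469, 0.28 and 0.556 under LINE1 ASO, above the 0.1 asked for in all 3 pairs, but not in all pairs of any other comparison, so the replicate block is given beside the siDux counts. The labels say nothing of shared cultures or days. CPM values are counts over the gene total of the library, scaled by TMM, with SD over 3 libraries, and repeat CPM uses the same gene totals.

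Genes were tested with edgeR 4.0.16 in R 4.3.3. Genes with too few counts were left out with filterByExpr by group, which left 14696 genes. Counts were scaled with TMM, and a quasi-likelihood model with one term per group was fitted to all 15 libraries (10 residual degrees of freedom). Repeats were tested the same way with library sizes and TMM factors of the gene table, which left 803 subfamilies. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05, and errors of log2 changes are the SE that the quasi-likelihood F statistic gives. The 7 comparisons are LINE1 ASO against RC ASO under siControl and under siDux, siNcl against siControl under RC ASO, siDux against siControl under RC ASO and under LINE1 ASO, the interaction of ASO and siDux, and LINE1 ASO with siControl directly against RC ASO with siNcl. The comparisons, the tests, the gene lists and the rule for naming genes were chosen before the data were examined.

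Lists of genes (18) were tested with camera (limma 3.58.1) at its preset correlation of 0.01, adjusted over the 126 pairs of list and comparison, and again with the correlation estimated per list. They hold 2-cell-like genes, pluripotency factors, genes of ribosome biogenesis and RNA polymerase I, cytosolic ribosomal proteins, p53 targets, the integrated stress response (ATF4), the interferon response, markers of endoderm, mesoderm and primitive streak, epiblast and neuroectoderm, trophoblast, germline genes, fibroblast markers, replication-dependent histones, S-phase genes, G2/M genes, cholesterol biosynthesis and translation factors. A list needed 5 tested members. The 9 groups of repeats gave 63 pairs, adjusted together. At the preset correlation 63 of the 126 list pairs passed and with an estimated correlation 3 did, and of the repeat groups 16 and 3 passed. List-wise counts use Benjamini-Hochberg over the members only.

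The names given are fixed ones (Dux, Ncl, Trim28, Zscan4c, Zscan4d, Zfp352, Pou5f1, Sox2, Nanog, Cdkn1a, L1Md subfamilies, MERVL-int, MT2_Mm, IAPEz-int), up to 8 genes per direction with the largest change among those called with at least 5 CPM in the higher group and no overlap between its libraries and those of the other, up to 4 members per list with the smallest p, and up to 5 repeats per direction with a mean of at least 100 counts. MLT1G3 and MLT1G fall outside this rule and were chosen after their values were seen, since few repeats were called in their comparisons. Some genes within the rule are not reported here.

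Alternatives fixed beforehand were RLE scaling, no filter, a filter of 5 CPM (100 counts for repeats), the replicate number as a block, a fit on the compared groups only, each library left out in turn, own library sizes and TMM for repeats, and DESeq2 1.42.0 (Wald test). Scaling to the summed ERCC counts, thinning of all libraries to the smallest gene total and the medians of lists under other scalings were chosen after the data had been seen. ERCC counts carry an error of pipetting of their own. Correlations between comparisons with shared controls were set against 50 simulations of unchanged groups with the dispersions of the data, 10 of which were also tested for calls, which does not bear on the overlap of calls, since unchanged groups give hardly any.

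The main test was tested on simulated data with changes put into 200 genes and 60 repeats. For LINE1 ASO against RC ASO under siControl it found 35.4%, 78.8% and 98.5% of genes changed 1.5-fold, 2-fold and 4-fold, with 8 false calls among 148, and 60%, 85% and 95% of repeats, with 4 false calls among 52. For the interaction it found 15.2%, 53% and 93.8% of genes, with 5 false calls among 111. Where nothing was changed, edgeR made 0 calls.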

Results

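RNA came from mouse E14 embryonic stem (ES) cells given an antisense oligonucleotide (ASO), then an siRNA after 7 h, and collected on day 2. The ASO was directed at LINE1, the most abundant family of mobile elements in the mouse genome, or was the control called RC. The siRNA was a control (siControl) or was directed at Dux or at Ncl. The 15 libraries formed 5 groups of 3, called here RC control (RC ASO with siControl), RC siDux, RC siNcl, LINE1 control (LINE1 ASO with siControl) and LINE1 siDux. Counts per gene summed to 10.1 M to 17.4 M per library in RC control, 11.5 M to 15.7 M in RC siDux and 9.55 M to 14.9 M in RC siNcl. They were deeper with LINE1 ASO, from 17.4 M upwards in LINE1 control and from 22.7 M to 27.6 M in LINE1 siDux. Reads on repeats, counted per subfamily, came to between 5.81% and 8.49% of the gene counts. RC control replicate 2 stood apart in TMM factor (0.874, others 0.965 to 1.07) and top 10 genes (6.24% of counts, others at most 5.35%). The 3 RC control libraries, baseline of the first 3 comparisons, lay lowest on the first principal component (-41.3, -59.4 and -35.2, others from -22.4). Changes these comparisons share may come partly from that baseline. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

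Ncl, which encodes the nucleolar RNA-binding protein nucleolin, was at 593 ± 67.7 CPM (SD, n = 3) in RC siNcl and at 5130 ± 932 CPM in RC control. Each RC siNcl library lay between 516 and 644 CPM and every other library at or above 3222 CPM. The means were 3937 ± 29.1 CPM in RC siDux, 3727 ± 484 CPM in LINE1 control and 3449 ± 238 CPM in LINE1 siDux. Dux, the transcription factor gene that switches on the 2-cell-like programme, had 4, 1 and 3 counts in RC control, 2, 0 and 5 in RC siDux, 25, 18 and 24 in LINE1 control, 19, 11 and 12 in LINE1 siDux and 13, 9 and 30 in RC siNcl. A knockdown of Dux under RC ASO was not detectable at this depth (log2 change -0.29 ± 0.83 SE, adjusted p = 0.862). Under LINE1 ASO, Dux was at 0.538 ± 0.0941 CPM with siDux and at 1.16 ± 0.299 CPM without it, a difference that did not pass the test (log2 change -1.07 ± 0.41, adjusted p = 0.298). Values of the near-identical Dux, Zscan4, Tcstv and Dub genes are uncertain, since how reads with several matches were counted is not given. The L1Md subfamilies, the young LINE1 elements of the mouse, summed to 4988 ± 1660 CPM in RC control (6841, 3623 and 4501 CPM), 7746 ± 1910 in RC siDux, 7611 ± 1490 in RC siNcl, 7067 ± 1520 in LINE1 control and 7819 ± 1520 in LINE1 siDux. L1Md counts were not lower in the libraries labelled LINE1 ASO, so they do not check that label, and directions given for LINE1 ASO rest on the labels.

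**Figure D1:**
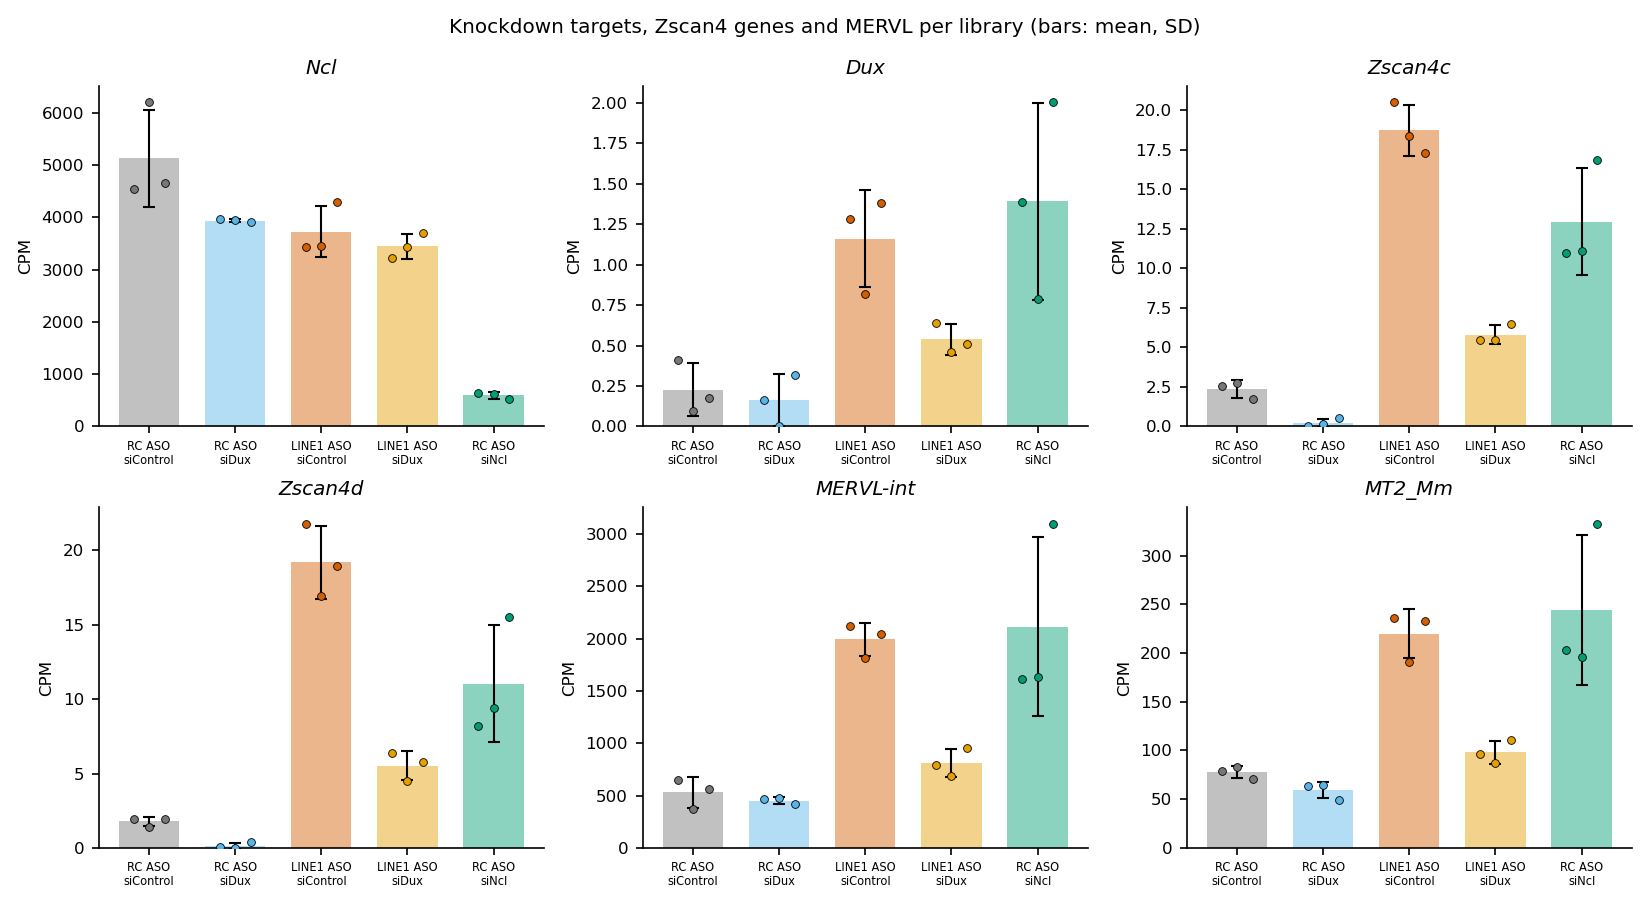
Levels in CPM (vertical axis) of Ncl, Dux, Zscan4c, Zscan4d and the repeats MERVL-int and MT2_Mm in each of the 5 groups. Bars are means, error bars SD and points the 3 libraries. Ncl is lowest in the RC siNcl libraries (593 CPM), and Zscan4c is highest in LINE1 control (18.7 CPM) and lowest in RC siDux (0.230 CPM).

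**Figure D2:**
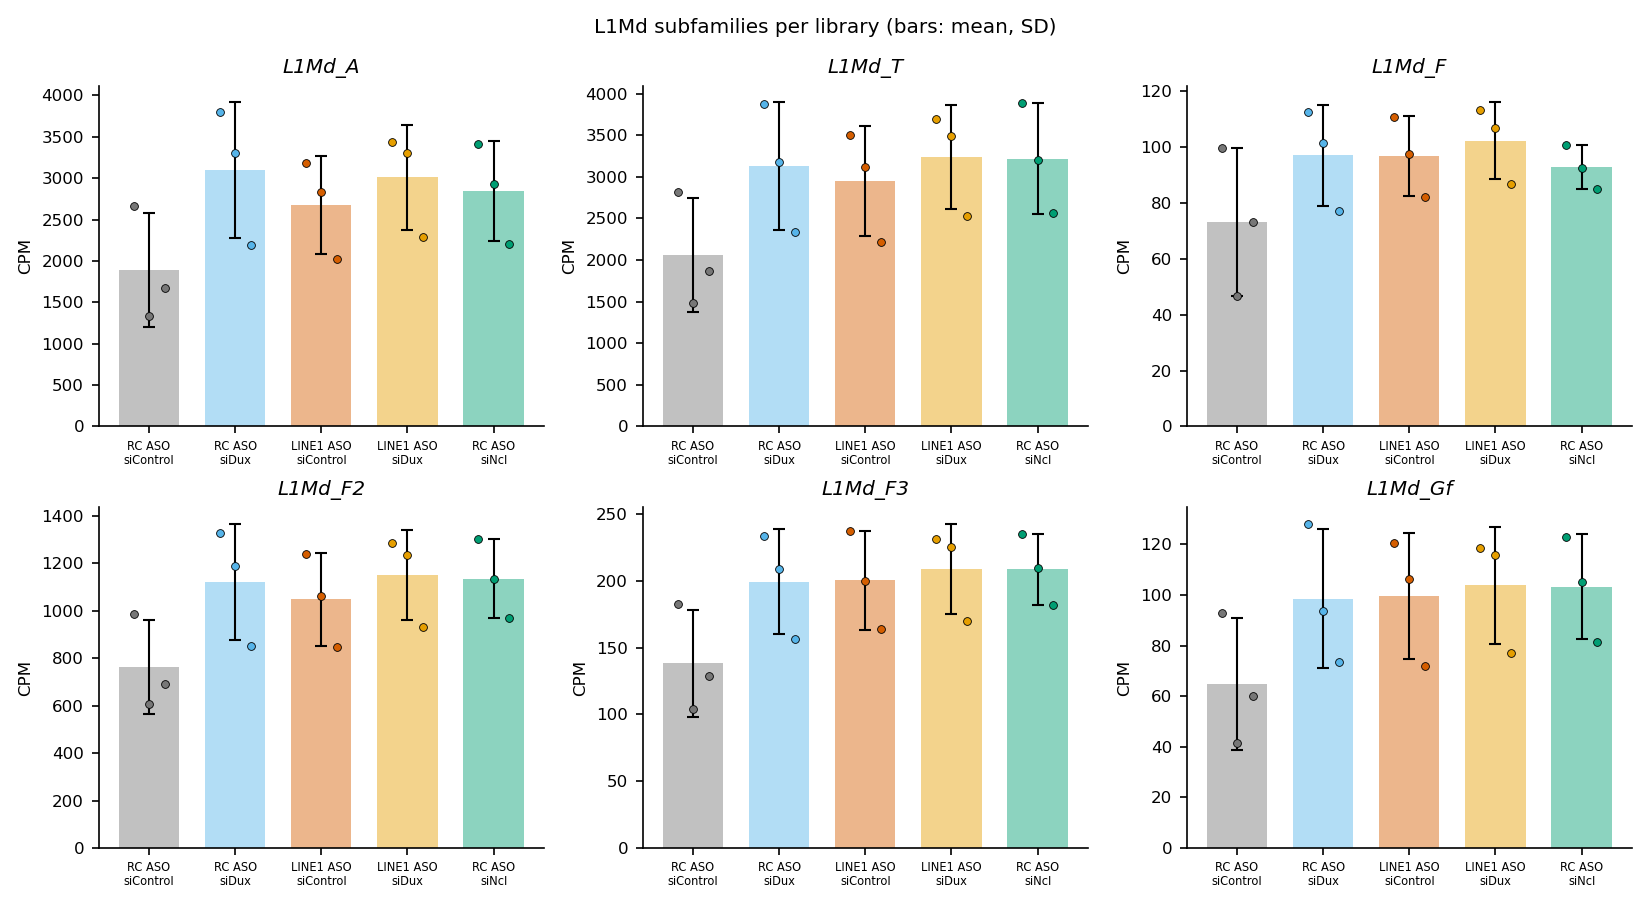
Levels in CPM (vertical axis) of the 6 L1Md subfamilies in each of the 5 groups. Bars are means, error bars SD and points the 3 libraries. Summed over the 6, RC control has the lowest mean (4988 CPM) and replicate 1 is the highest library in each group.

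The first comparison asked what differs when the LINE1 ASO takes the place of the RC ASO under siControl. Genes of the 2-cell-like state, a rare state of ES cells in which genes of the 2-cell embryo are transcribed, rose in the libraries labelled LINE1 ASO. Of the 34 members measured, 32 rose (32 adjusted over the list alone, or list-wise), with a median log2 change of 2.29, a 4.88-fold rise. Zscan4c, which belongs to a gene cluster transcribed in 2-cell embryos, went from 2.36 ± 0.557 to 18.7 ± 1.63 CPM (SD, n = 3 in each group), a log2 change of 3.03 ± 0.28 (SE, adjusted p = 6.78e-06). Zscan4d rose by 3.41 ± 0.30 (adjusted p = 5.53e-06), Zscan4f by 3.47 ± 0.30 and Tcstv3, another gene of 2-cell embryos, by 2.75 ± 0.24 on the log2 scale. Gm12794 rose by 3.20 ± 0.28 and the deubiquitinase gene Dub1 by 2.85 ± 0.25. Dux rose by 2.36 ± 0.57 (adjusted p = 0.0128), a call that was lost without LINE1 control replicate 1 (log2 change 2.29). Zfp352, a zinc finger gene of the same state, did not pass (0.85 ± 0.40, adjusted p = 0.146). The list as a set stood above the other genes (camera, adjusted p = 2.77e-50). With an estimated correlation it did not pass (adjusted p = 0.0642).

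Outside that list, the largest rises among well-counted genes included Arhgef33, which encodes a guanine nucleotide exchange factor (log2 change 3.92 ± 0.30, adjusted p = 3.54e-06), the carboxypeptidase gene Cpz (3.02 ± 0.28) and the cartilage matrix gene Matn1 (2.93 ± 0.22). Among 31 targets of the tumour suppressor p53, 14 rose (19 rose and 2 fell list-wise), with a list median of 0.43. Mdm2, which encodes the ubiquitin ligase of p53, rose by 1.17 ± 0.14 (adjusted p = 9.05e-05), Trp53inp1 by 1.19 ± 0.12, the epoxide hydrolase gene Ephx1 by 1.03 ± 0.12 and the receptor gene Eda2r by 0.74 ± 0.11. Cdkn1a, which encodes the cell cycle inhibitor p21, did not pass (0.57 ± 0.20, adjusted p = 0.0587), but did with DESeq2, with no filter, with the stricter filter, with the replicate block, in a fit on the 6 libraries compared and after thinning (log2 changes from 0.56 to 0.63). The p53 list passed as a set (adjusted p = 1.7e-10), a call lost (adjusted p = 0.213 with an estimated correlation), and 9 of its members rose when LINE1 control replicate 1 was left out.

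Genes of protein synthesis fell by small amounts. Of 76 cytosolic ribosomal protein genes, 62 fell (69 list-wise), with a median log2 change of -0.52, and Rpl23a (-0.58 ± 0.13, adjusted p = 0.00837) and Fau (-0.63 ± 0.15, adjusted p = 0.0118) are examples. Random lists of other genes, not fully matched on length and expression, fell too (median -0.38). The lists below had no such comparison. In the list of ribosome biogenesis and RNA polymerase I, 30 of 65 fell (40 fell and 1 rose list-wise, median -0.29), among them the polymerase subunit gene Polr1c (-0.53 ± 0.11). Of 30 translation factors 17 fell (21 list-wise, median -0.31), among them Eif2s2 (-0.60 ± 0.11) and Eif3g (-0.52 ± 0.10). Of 22 genes of cholesterol biosynthesis 14 fell (16 list-wise, median -0.44), such as Fdft1 (-0.47 ± 0.09), Fdps (-0.68 ± 0.14) and Srebf2, which encodes the regulator of the pathway (-0.50 ± 0.10). These lists passed as sets (adjusted p = 1.22e-21, 6.71e-11, 4.17e-09 and 5.98e-09), and these calls were lost (adjusted p = 0.403, 0.4, 0.384 and 0.203 with an estimated correlation). Without RC control replicate 2, which stood apart, 28 ribosomal protein genes, 14 of ribosome biogenesis and 9 translation factors fell. The ribosomal protein median was then -0.26. Without LINE1 control replicate 1, edgeR called 0 ribosomal protein genes lower (63 at an unadjusted p under 0.05, list median -0.44), 1 of ribosome biogenesis, 3 translation factors and 5 cholesterol genes. The calls of Rpl23a (-0.51) and Fau (-0.52) were then lost. Without LINE1 control replicate 2 the counts were 2, 3, 4 and 9.

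Among 26 pluripotency factors 8 fell (8 list-wise, median -0.20), including Pou5f1, which encodes Oct4 (-0.65 ± 0.13, adjusted p = 0.00445), and Utf1 (-0.70 ± 0.14). Nanog did not pass (-0.12 ± 0.17, adjusted p = 0.643). Among 29 genes of the integrated stress response 8 fell and 1 rose (10 and 2 list-wise), such as the serine synthesis gene Psat1 (-0.69 ± 0.13) and the alanyl-tRNA synthetase gene Aars (-0.49 ± 0.09). The median of this list was -0.17 and turned to 0.04 with scaling to the ERCC spike-ins (-0.18 relative to all genes). Of 26 interferon-response genes 7 fell and 1 rose (7 and 2 list-wise, median -0.38), with Bst2 (-0.91 ± 0.15) and Parp14 (-0.77 ± 0.16) as examples. In the G2/M list of 30 genes 4 fell and 1 rose (4 and 1 list-wise), among them Hmmr (-0.39 ± 0.08), with a median of -0.12 that turned to 0.08 with ERCC scaling (-0.13 relative to all genes). These 4 lists passed as sets (adjusted p = 0.00716, 0.000995, 0.0186 and 0.0257), and these calls were lost (adjusted p = 0.461, 0.552, 0.203 and 0.518 with an estimated correlation). The number of pluripotency genes that fell was 2 without RC control replicate 2 or LINE1 control replicate 1 or 2. For interferon genes it was 4 without RC control replicate 1 or 3 and 2 without LINE1 control replicate 1 or 2. For G2/M genes it was 2 without RC control replicate 2, 7 without RC control replicate 3, and 1, 2 and 9 without LINE1 control replicates 1, 2 and 3. The median of the stress-response list was -0.26 and -0.10 without RC control replicates 2 and 3 and -0.28 and -0.08 without LINE1 control replicates 1 and 3. That of the interferon list was -0.24 without RC control replicate 3, and that of the G2/M list -0.05 without RC control replicate 2.

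Markers of endoderm (median 0.40, adjusted p = 0.199), mesoderm (0.28, 0.26), epiblast and neuroectoderm (0.11, 0.951) and trophoblast (0.22, 0.124) did not pass as sets, and neither did germline genes (0.10, 0.256), fibroblast markers (-0.11, 0.714), histones (0.23, 0.605) or S-phase genes (-0.04, 0.373). With ERCC scaling the fibroblast median turned to 0.08 and the S-phase one to 0.15 (-0.14 and -0.07 relative to all genes), and the epiblast median turned to -0.06 without RC control replicate 2. Without that library the medians of endoderm, mesoderm and S-phase genes were 0.13, 0.16 and -0.00 and those of histones and germline genes 0.56 and 0.16. With libraries left out the mesoderm median ran from 0.14 to 0.67, the epiblast one from -0.11 to 0.46 and the fibroblast one from -0.13 to 0.07. Of the endoderm markers 4 rose and 2 fell, of the germline genes 3 rose and 1 fell, and of the S-phase genes 1 rose and 3 fell. In the trophoblast list 4 rose, in the mesoderm list 3 rose, and in the epiblast and fibroblast lists 1 each fell. With libraries left out, the members that rose numbered 2 to 5 for endoderm (2 without RC control replicate 2), 2 to 5 for germline genes, 1 to 3 for trophoblast and at most 3 for mesoderm, and at most 5 S-phase genes fell. Members of these lists that rose include the endoderm receptor gene Cubn (1.43 ± 0.24, adjusted p = 0.00152), the transcription factor gene Sox21 of the trophoblast list (1.32 ± 0.22) and the germline gene Taf7l (1.19 ± 0.21). Egln3, which encodes an oxygen-sensing prolyl hydroxylase, was among the largest falls (-1.39 ± 0.27, adjusted p = 0.00431). Ncl fell by 0.46 ± 0.12 (adjusted p = 0.0208), a call lost without RC control replicate 2 (-0.30), LINE1 control replicate 1 (-0.39) or LINE1 control replicate 2 (-0.40). Trim28, which encodes a corepressor of retrotransposons, fell by 0.44 ± 0.11 (adjusted p = 0.0164), a call lost without LINE1 control replicate 1 (-0.32) or LINE1 control replicate 2 (-0.41).

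In repeat RNA the strongest rise was that of MERVL, the endogenous retrovirus transcribed with the 2-cell-like genes. MERVL-int went from 530 ± 144 to 1993 ± 161 CPM (log2 change 1.91 ± 0.23, adjusted p = 4.01e-05), and its promoter repeat MT2_Mm rose by 1.51 ± 0.18 (adjusted p = 4.01e-05). The MERVL group passed (3 of 3 rose, adjusted p = 1.22e-08) and did so too with an estimated correlation (adjusted p = 0.0474). The retroviral repeat RLTR6_Mm rose by 1.06 ± 0.16 and IAPEz-int, of the IAP retrotransposons, by 0.56 ± 0.11 (adjusted p = 0.00724), a call lost when repeats were scaled by their own totals and in a fit on the 6 libraries compared. The 6 L1Md subfamilies did not pass singly, with log2 changes from 0.41 for L1Md_F (adjusted p = 0.211) to 0.62 for L1Md_Gf (adjusted p = 0.146), nor as a group (median 0.51, adjusted p = 0.0983, and adjusted p = 0.00464 with the replicate block). Without RC control replicate 1 each of the 6 passed, with log2 changes from 0.69 for L1Md_F to 0.97 for L1Md_Gf. With the replicate block all but L1Md_F passed, and L1Md_F3 passed without LINE1 control replicate 3 (0.67). The older L1 group passed (6 of 84 rose and 1 fell, median 0.38, adjusted p = 0.000286), a call lost (adjusted p = 0.949 with an estimated correlation). The groups of IAP (median 0.31, adjusted p = 0.129), ETn and MusD (0.44, 0.129), MaLR (0.12, 0.632), B1 (0.02, 0.46), B2 and B3 (-0.13, 0.103) and satellite repeats (0.36, 0.797) did not pass, and for MaLR and B1 the test pointed down. In all, 40 of 803 subfamilies rose and 7 fell, and the median of all subfamilies was 0.20. The number that rose was 84 without RC control replicate 1, 25 without RC control replicate 2, and 10, 23 and 91 without LINE1 control replicates 1, 2 and 3. The number that fell was 23, 2 and 24 without RC control replicates 1, 2 and 3 and 1, 1 and 12 without LINE1 control replicates 1, 2 and 3.

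Of 14696 genes tested, 1374 rose and 1424 fell in this comparison (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 507 and 61 of them changed at least 2-fold. Leaving out LINE1 control replicate 1 gave 473 higher and 113 lower genes, leaving out LINE1 control replicate 2 gave 637 and 239, leaving out RC control replicate 2 gave 703 lower genes, and a fit on the 6 libraries compared gave 364 and 32. That fit ended the calls of Ncl, Trim28, Pou5f1, Utf1, Rpl23a, Fau, Polr1c, Eif2s2, Eif3g, Fdft1, Fdps, Srebf2, Aars, Parp14 and Hmmr. With scaling to the ERCC spike-ins the median of all genes was at 0.22 and 278 genes were higher and 2 lower. Relative to that median the 2-cell-like list stood at 2.29, the p53 list at 0.41 and the ribosomal protein list at -0.47, and the calls of Mdm2, Ephx1, Eda2r, Taf7l and of the genes named above as fallen ended.

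**Figure D3:**
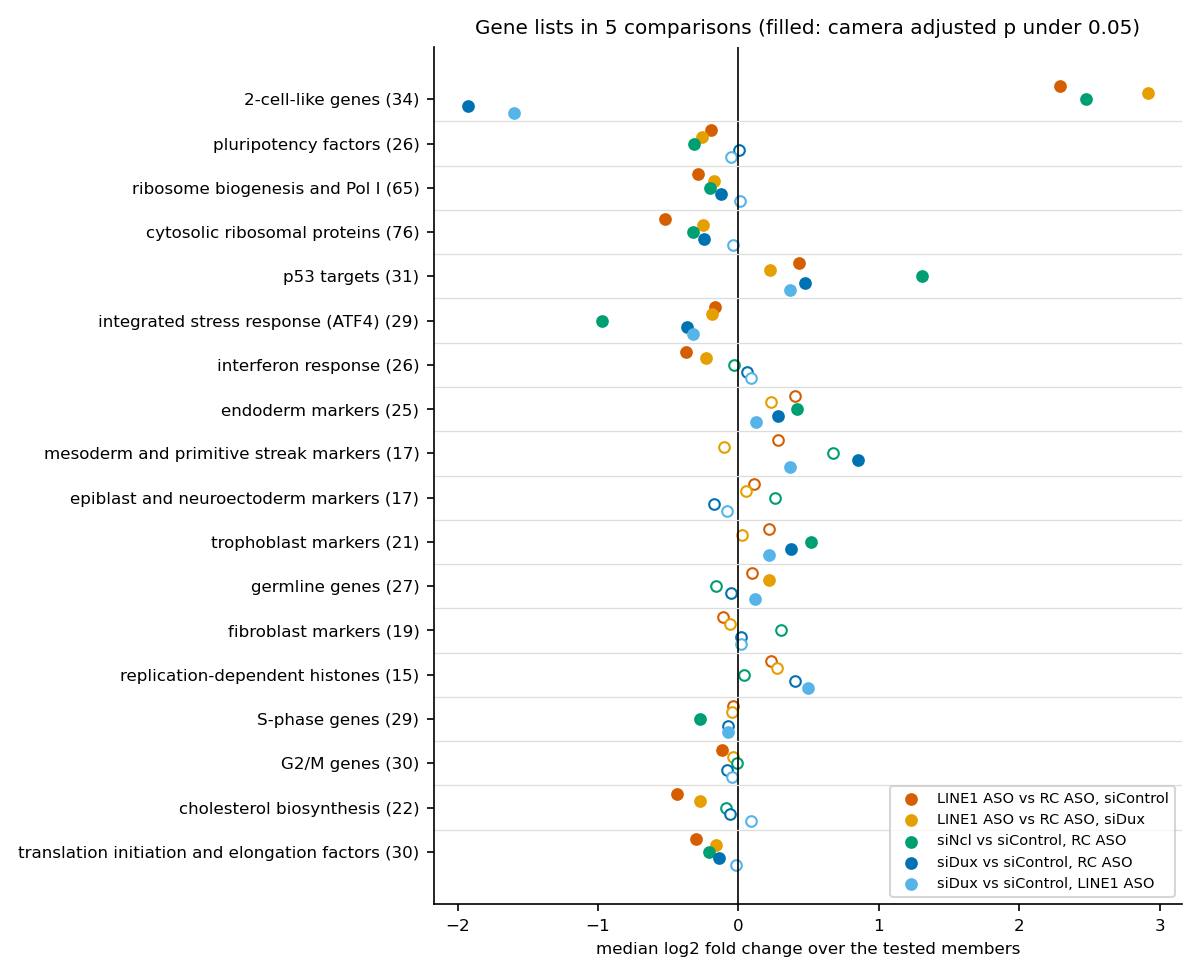
Median log2 fold change (horizontal axis) of each of the 18 gene lists (vertical axis) in 5 comparisons, with filled points where the list passed the camera test at its preset correlation. The 2-cell-like list lies at 2.29 for LINE1 ASO under siControl and 2.48 for siNcl, and at -1.93 for siDux under RC ASO.

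The second comparison asked what follows loss of nucleolin, with RC siNcl set against RC control. Ncl fell by 3.11 ± 0.14 on the log2 scale (adjusted p = 8.81e-10, n = 3 in each group). The 2-cell-like genes rose here too, 33 of 34 (33 list-wise), with a median log2 change of 2.48, a 5.56-fold rise. Zscan4c rose from 2.36 ± 0.557 to 13.0 ± 3.36 CPM (log2 change 2.51 ± 0.28, adjusted p = 6.42e-06), Zscan4d by 2.63 ± 0.31, Zscan4f by 2.88 ± 0.31 and Tcstv3 by 2.37 ± 0.24. Dux rose by 2.67 ± 0.58 (adjusted p = 0.00225) and Zfp750, a list member known as a regulator of epidermal differentiation, by 2.80 ± 0.21. Zfp352 did not pass (0.72 ± 0.42, adjusted p = 0.206). Of 31 p53 targets 24 rose (26 rose and 1 fell list-wise), with a median of 1.31. Mdm2 went from 156 ± 13.8 to 916 ± 107 CPM (log2 change 2.55 ± 0.15, adjusted p = 5.16e-09), Trp53inp1 rose by 2.18 ± 0.12, Ephx1 by 1.96 ± 0.12, the DNA polymerase gene Polk by 1.53 ± 0.11 and Cdkn1a by 1.54 ± 0.20 (adjusted p = 3.09e-05). Both lists passed as sets (adjusted p = 6.03e-23 and 4.88e-31). The p53 list did so too with an estimated correlation (adjusted p = 0.0411) and the 2-cell-like list did not (adjusted p = 0.213).

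The largest rises among well-counted genes included the leukotriene receptor gene Ltb4r2 (log2 change 5.05 ± 0.39, adjusted p = 1.14e-07), the apolipoprotein gene Apol8 (4.38 ± 0.43) and Cpz (4.22 ± 0.28). Among them were also the vitamin D receptor gene Vdr (4.12 ± 0.38), the epidermal caspase gene Casp14 (3.90 ± 0.30), Arhgef33 (3.85 ± 0.31) and the leukocyte integrin gene Itgb2 (3.76 ± 0.53). The largest falls included Zc3h6 (-3.14 ± 0.41, adjusted p = 3.14e-05), Rnf157 (-2.34 ± 0.30) and Mipol1 (-2.31 ± 0.26). Genes of the integrated stress response fell, 22 of 29 with 1 that rose (24 and 1 list-wise), with a median of -0.97. Nupr1 fell by 2.26 ± 0.35 and Chac1, a glutathione-degrading enzyme gene, by 2.28 ± 0.62 (adjusted p = 0.0105), and the tRNA synthetase genes Aars (-1.24 ± 0.09), Nars (-1.14 ± 0.10) and Sars (-1.38 ± 0.13) and the serine synthesis gene Psat1 (-1.26 ± 0.13) fell as well. The list passed as a set (adjusted p = 1.09e-14), a call lost (adjusted p = 0.203 with an estimated correlation).

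Of 26 pluripotency factors 12 fell and 1 rose (12 and 2 list-wise, median -0.32), among them Zfp42 (-0.80 ± 0.14), Pou5f1 (-0.68 ± 0.13, adjusted p = 0.000739), Lin28a (-0.63 ± 0.09) and Nr0b1 (-1.41 ± 0.29). Sox2 (-0.12 ± 0.09, adjusted p = 0.335) and Nanog (0.17 ± 0.17, adjusted p = 0.481) did not pass. Of 29 S-phase genes 13 fell and 1 rose (15 and 1 list-wise, median -0.27), with the replication genes Pcna (-0.78 ± 0.10), Cdc6 (-0.59 ± 0.09) and Mcm4 (-0.39 ± 0.06). Of 76 ribosomal protein genes 23 fell (15 list-wise, median -0.33), such as Rpl3 (-0.96 ± 0.12) and Rps20 (-1.06 ± 0.24). In ribosome biogenesis 20 of 65 fell and 4 rose (20 and 4 list-wise, median -0.21), with the polymerase I factor gene Ubtf (-0.76 ± 0.10) and Polr1c (-0.79 ± 0.11) falling and Utp20 (0.73 ± 0.09) rising. Of the translation factors 10 of 30 fell (10 list-wise, median -0.21), among them Eif3d (-0.64 ± 0.10). These 5 lists passed as sets (adjusted p = 0.00345, 0.000149, 1.06e-05, 0.00345 and 0.00539), and these calls were lost (adjusted p = 0.411, 0.437, 0.667, 0.667 and 0.661 with an estimated correlation). The number of ribosomal protein genes that fell was 41, 8 and 47 without RC control replicates 1, 2 and 3 and 11, 9 and 7 without RC siNcl replicates 1, 2 and 3. It was 10 for ribosome biogenesis without RC siNcl replicate 3, and for translation factors 5 without RC control replicate 2 and 5, 4 and 3 without RC siNcl replicates 1, 2 and 3. Without RC control replicate 2 the medians of ribosomal proteins, ribosome biogenesis and translation factors were -0.10, -0.12 and -0.12.

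Markers of differentiated lineages rose in part. Of 21 trophoblast markers 8 rose and 1 fell (8 and 1 list-wise, median 0.51), including the transcription factor genes Gcm1 (2.76 ± 0.35, adjusted p = 2.43e-05) and Tfap2c (1.08 ± 0.14). Of 25 endoderm markers 9 rose (9 list-wise, median 0.42), including Foxa1 (1.95 ± 0.40) and the basement membrane collagen gene Col4a1 (0.71 ± 0.13). Both lists passed as sets (adjusted p = 0.0145 and 0.0408), and both calls were lost (adjusted p = 0.305 and 0.411 with an estimated correlation). Of 17 mesoderm markers 6 rose (6 list-wise, median 0.67), with Wnt3a (2.10 ± 0.49) and Mesp2 (1.55 ± 0.31), but the list did not pass (adjusted p = 0.12). The lists of epiblast and neuroectoderm, germline, fibroblast, G2/M, cholesterol, histone and interferon genes did not pass (adjusted p from 0.239 to 0.982). In them 2 epiblast markers rose and 3 fell, 3 germline genes rose and 5 fell, 2 fibroblast markers rose and 1 fell, 6 G2/M genes rose and 4 fell, 1 cholesterol gene rose and 3 fell, and 3 interferon genes rose and 3 fell. With libraries left out 2 to 7 G2/M genes rose and 2 to 6 fell, and 3 to 6 germline genes fell. Within them Neurog2, a neuronal transcription factor gene, rose by 4.41 ± 0.71 and Zic2 fell by 0.82 ± 0.17, Dmrtb1 rose by 1.49 ± 0.20 and Tuba3a fell by 1.02 ± 0.20, Mmp2 rose by 1.30 ± 0.22, and Cenpe rose by 0.45 ± 0.08. For interferon genes the median was -0.03 and the mean 0.13 with a test pointing down, for histones the median was 0.04 and the mean -0.03 with a test pointing down, and for G2/M genes the median was -0.01 with a test pointing up. These medians turned with single libraries left out, from -0.20 to 0.27 for interferon genes, from -0.18 to 0.24 for histones and from -0.05 to 0.03 for G2/M genes, and the mesoderm median ran from 0.44 to 0.94. Trim28 fell by 0.55 ± 0.11 (adjusted p = 0.00144).

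MERVL rose in RC siNcl as well. MERVL-int went from 530 ± 144 to 2116 ± 852 CPM (log2 change 2.00 ± 0.23, adjusted p = 2.18e-05), MT2_Mm rose by 1.66 ± 0.18 and MT2C_Mm by 0.98 ± 0.12. The MERVL group passed (3 of 3 rose, adjusted p = 1.52e-09, and adjusted p = 0.0474 with an estimated correlation). The simple repeat (TTA)n rose by 1.20 ± 0.15, (CAT)n fell by 1.14 ± 0.14 and the short interspersed element B2_Mm1a by 0.78 ± 0.15, a call lost in a fit on the 6 libraries compared. IAPEz-int rose by 0.51 ± 0.11 (adjusted p = 0.00841), a call lost in that fit, with repeats scaled by their own totals and without RC siNcl replicate 3 (0.42). L1Md (median 0.59, adjusted p = 0.0326), older L1 (median 0.32, adjusted p = 0.00902) and ETn and MusD (median 0.49, adjusted p = 0.0474) passed upwards and B2 and B3 downwards (median -0.12, adjusted p = 0.0259). These calls were lost (adjusted p = 0.949, 0.949, 0.805 and 0.713 with an estimated correlation). In all 49 subfamilies rose and 11 fell, and the number that rose was 19, 28 and 27 without RC siNcl replicates 1, 2 and 3. The number that fell was 23 and 24 without RC control replicates 1 and 3 and 6, 7 and 5 without RC siNcl replicates 1, 2 and 3.

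Over all genes 2461 rose and 2298 fell with siNcl, 977 and 334 of them at least 2-fold, by the same test. Without RC siNcl replicate 3, 1487 fell, and a fit on the 6 libraries compared called 1240 lower. With ERCC scaling 563 genes were higher and 68 lower, and the calls of Trim28, Tfap2c, Col4a1, Cenpe, Utp20, Tuba3a, Zic2 and of the tRNA synthetase, Psat1, pluripotency, S-phase, ribosomal protein, Ubtf, Polr1c and Eif3d falls named above ended, while Ncl, Zscan4c, Mdm2, Cdkn1a and Chac1 passed.

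The LINE1 ASO and siNcl comparisons share their 3 controls, and their log2 changes were correlated across genes (Pearson r = 0.692, Spearman correlation = 0.595, genes not being independent replicates). In 50 simulations of unchanged groups, with controls drawn anew but shared by both comparisons, the mean r was 0.536 and the mean Spearman correlation 0.478. The covariance was 0.270, against a simulated mean of 0.0461, a difference of 0.224. Both comparisons called 867 genes higher, 63.1% of those higher with LINE1 ASO, and 795 lower, 55.8%, where independent lists of these sizes would share 230 and 223, and 24 genes were called in opposite directions. Of all genes 72.5% had the same sign, against 67.3% in simulation. Part of the excess may come from the shared controls, since 3 libraries cannot be split into parts of at least 2. The shared higher genes numbered 397 without LINE1 control replicate 1 and 502 without LINE1 control replicate 2. The shared lower genes numbered 85 and 166 without those libraries, 355 without RC control replicate 2, 1232 without RC control replicate 3 and 505 without RC siNcl replicate 3.

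**Figure D4:**
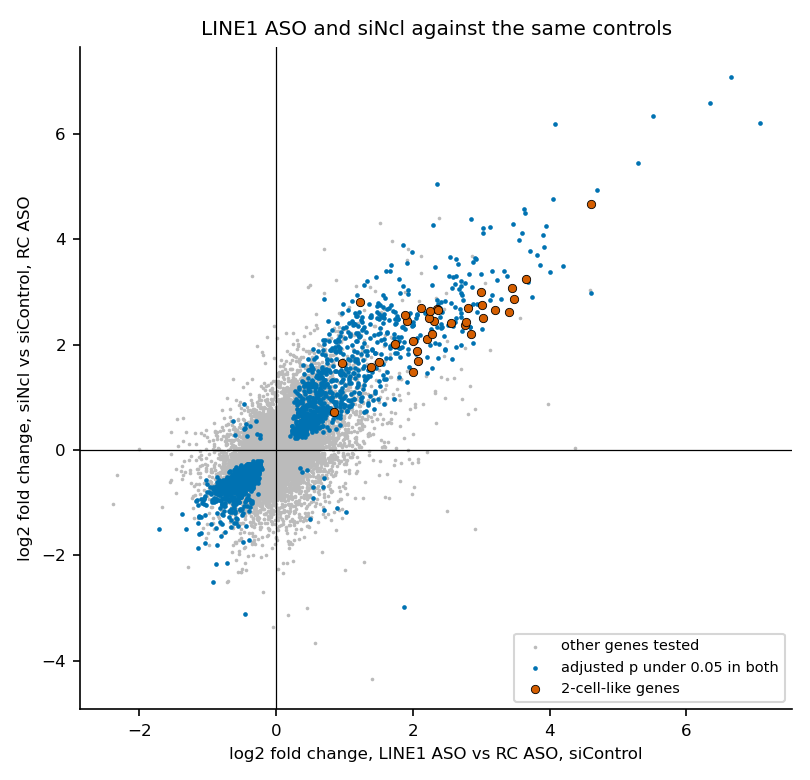
Log2 fold change of each gene tested for LINE1 ASO against RC ASO under siControl (horizontal axis) and for siNcl against siControl under RC ASO (vertical axis), both against the same 3 control libraries. Grey points are single genes, blue points genes with an adjusted p under 0.05 in both, and orange points the 2-cell-like genes, which all lie in the upper right.

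Where the LINE1 ASO and siNcl effects differ was tested by setting LINE1 control directly against RC siNcl, in which the shared controls drop out. The 2-cell-like list did not differ as a set (median 0.09, adjusted p = 0.572), and neither did Zscan4c (0.52 ± 0.23) or Dux (-0.30 ± 0.40, adjusted p = 0.651), which does not show that they were equal. The list median was 0.57 without RC siNcl replicate 3, with 5 members higher and 1 lower, 0.01 without LINE1 control replicate 3, and -0.08 and -0.11 without RC siNcl replicates 1 and 2. In a fit on the 6 libraries compared, Zscan4c passed. Zfp750 of this list was lower in LINE1 control (-1.58 ± 0.19). Besides Ncl (2.65 ± 0.13, adjusted p = 8.25e-09), genes higher in LINE1 control included the apoptosis gene Hrk (3.41 ± 0.60, adjusted p = 0.000857), Zc3h6 (3.31 ± 0.41), Chac1 (3.29 ± 0.62), Rnf157 (2.43 ± 0.30) and Nupr1 (2.29 ± 0.35). Within LINE1 control the 3 libraries ranged from 18.4 to 86.1 CPM for Chac1 and from 3.63 to 15.1 CPM for Hrk. Lower were Ltb4r2 (-2.70 ± 0.29, adjusted p = 1.46e-05), the neurotrophic receptor gene Gfra3 (-2.64 ± 0.33), the neuronal gene Neurod1 (-2.18 ± 0.18), Casp14 (-2.04 ± 0.24), Oasl2 (-1.98 ± 0.42) and Rtkn (-1.88 ± 0.21).

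Of 31 p53 targets 21 were lower in LINE1 control than in RC siNcl (22 list-wise, median -0.86), such as Perp (-1.74 ± 0.20), Mdm2 (-1.38 ± 0.14, adjusted p = 7.87e-06) and Cdkn1a (-0.98 ± 0.20). Of 29 genes of the integrated stress response 17 were higher and 1 lower (23 and 1 list-wise, median 0.57), with Mthfd2 (1.13 ± 0.14), Aldh18a1 (1.28 ± 0.16) and Aars (0.74 ± 0.09) as examples. Of 29 S-phase genes 10 were higher (13 list-wise, median 0.23), with Cdc6 (0.55 ± 0.09) and Pcna (0.51 ± 0.10). Cholesterol genes were lower, 9 of 22 (11 list-wise, median -0.28). These 4 lists passed as sets (adjusted p = 2.57e-20, 1.7e-11, 6.14e-05 and 0.000715), and these calls were lost (adjusted p = 0.0942, 0.224, 0.411 and 0.407 with an estimated correlation). Without LINE1 control replicates 1 and 2 the lower cholesterol genes numbered 3 and 4, and without RC siNcl replicates 1 and 2 they numbered 5 and 4.

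Interferon-response genes (6 of 26 lower, 6 list-wise, median -0.45), with Xaf1 (-0.93 ± 0.17) and Ifi35 (-0.84 ± 0.16), also passed in the direct test. So did G2/M genes (5 of 30 lower, 5 list-wise, median -0.10 and 0.05 with ERCC scaling), with Hmmr (-0.84 ± 0.08). Germline genes passed upwards (8 of 27 higher and 2 lower, 8 and 3 list-wise, median 0.31), with Mov10l1 (0.72 ± 0.14) higher and Dmrtb1 (-0.79 ± 0.18) lower. Their adjusted p was 0.0408, 0.0332 and 0.0421, and these calls were lost (adjusted p = 0.224, 0.552 and 0.605 with an estimated correlation). Ribosomal protein genes passed with 1 higher and 1 lower (1 and 0 list-wise, median -0.18, adjusted p = 0.00988), with Rpl3 as the higher one (0.61 ± 0.12), a call lost (adjusted p = 0.812 with an estimated correlation). The lower interferon genes numbered 3 without LINE1 control replicate 1 or 2 or RC siNcl replicate 1. The lower G2/M genes numbered 3 without any one of LINE1 control replicates 1 and 2 and RC siNcl replicates 1, 2 and 3, and the higher germline genes 1 and 5 without LINE1 control replicates 1 and 2 and 5, 3 and 2 without RC siNcl replicates 1, 2 and 3. Medians moved by over 1.5 times for interferon genes without RC siNcl replicate 3 (-0.16), for ribosomal proteins without LINE1 control replicate 1 (-0.11), and for G2/M genes without LINE1 control replicates 1 and 2 (-0.06 and -0.05) and RC siNcl replicate 1 (-0.06). The other lists did not pass. In them 5 pluripotency factors were higher and 2 lower, 3 epiblast and neuroectoderm markers higher and 3 lower, 4 endoderm markers higher and 5 lower (5 and 8 list-wise, adjusted p of the list 0.154), and 2 ribosome biogenesis genes higher and 8 lower (2 to 17 with libraries left out). Only lower were 5 trophoblast markers (list 0.0921), 3 fibroblast markers and 2 translation factors. With libraries left out at most 5 endoderm markers were higher and 2 to 5 trophoblast markers lower. Among pluripotency factors Nr0b1 was higher (1.39 ± 0.29) and Gdf3 lower (-0.55 ± 0.10), and among neuroectoderm markers Zic2 was higher (0.91 ± 0.17) and Neurog2 lower (-2.03 ± 0.47). Lower members of the endoderm and trophoblast lists included Col4a1 (-0.97 ± 0.13), Sparc (-0.72 ± 0.10), Tfap2c (-0.98 ± 0.14) and Gcm1 (-1.25 ± 0.29).

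Among repeats, Tigger6a was higher in LINE1 control (0.85 ± 0.17, adjusted p = 0.0313), and FordPrefect (-1.48 ± 0.30), SSU-rRNA_Hsa, which matches the small ribosomal RNA (-0.88 ± 0.11, adjusted p = 0.000239), and (TTA)n (-0.65 ± 0.14) were lower. Only the SSU-rRNA_Hsa call held whichever of the 6 libraries was left out. (TTA)n and FordPrefect lost theirs without any one of them, and Tigger6a without any one but LINE1 control replicate 3. Of all genes 1389 were higher and 1534 lower in the direct test. Leaving out LINE1 control replicate 1 gave 840 and 949, leaving out LINE1 control replicate 2 gave 819 and 911, RC siNcl replicate 1 gave 879 higher and RC siNcl replicate 3 gave 997 lower. With ERCC scaling the median of all genes was at 0.16 and 106 genes were higher and 19 lower. The p53 list then stood at -0.81 relative to all genes, and of the genes named Ncl, Hrk, Zc3h6, Chac1, Nupr1, Rnf157, Ltb4r2, Gfra3, Neurod1, Casp14, Oasl2, Rtkn, Perp and Nr0b1 passed while the other calls ended.

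The third comparison asked what siDux does without the LINE1 ASO, with RC siDux set against RC control. The 2-cell-like genes, already at low levels in RC control, fell. Of 34 members 16 fell and 1 rose (24 and 1 list-wise), with a median log2 change of -1.93. Zscan4c fell from 2.36 ± 0.557 to 0.230 ± 0.260 CPM (log2 change -3.14 ± 0.49, adjusted p = 0.000865, n = 3 in each group). Zscan4d fell by 3.29 ± 0.57, Tcstv3 by 2.52 ± 0.38 and Tcstv1 by 5.02 ± 0.56 (adjusted p = 8.63e-05), from 40, 77 and 72 counts to 1, 1 and 4. The member that rose was Zfp750 (1.80 ± 0.22, adjusted p = 0.000147). The list passed as a set (adjusted p = 5.5e-17), a call lost (adjusted p = 0.224 with an estimated correlation). Of 31 p53 targets 18 rose (21 list-wise, median 0.48), with Mdm2 (1.34 ± 0.14, adjusted p = 6e-05), Ptpn14 (1.47 ± 0.21), Btg2 (1.30 ± 0.18) and Ephx1 (0.94 ± 0.12). This list passed as a set (adjusted p = 3.86e-16), a call lost (adjusted p = 0.157 with an estimated correlation), and 10 of its members rose without RC siDux replicate 3.

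The largest rises with siDux included Apol8 (3.43 ± 0.45, adjusted p = 0.000288), the gluconeogenic enzyme gene Fbp1 (2.87 ± 0.43), the signalling gene Rtkn (2.42 ± 0.23), the phospholipase gene Plcd4 (2.32 ± 0.25) and Cpz (2.24 ± 0.29). The splicing protein gene Snrpe fell by 1.66 ± 0.28 and the interferon-induced gene Bst2 by 0.94 ± 0.15. Of 29 genes of the integrated stress response 7 fell (11 list-wise), such as Sars (-0.65 ± 0.13) and Nars (-0.46 ± 0.10), with a median of -0.36 that was -0.01 with ERCC scaling (-0.32 relative to all genes). Mesoderm markers passed upwards (3 of 17 rose, 5 list-wise, median 0.85), with the endothelial receptor gene Kdr (2.14 ± 0.29) and Wnt3a (2.40 ± 0.47). So did trophoblast markers (3 of 21, 4 list-wise, median 0.38), with Gcm1 (2.36 ± 0.36), and endoderm markers (5 of 25, 5 list-wise, median 0.28), with Col4a1 (0.78 ± 0.13). The adjusted p of these 4 lists was 6.78e-06, 0.00132, 0.00194 and 0.00725, and these calls were lost (adjusted p = 0.411, 0.263, 0.213 and 0.305 with an estimated correlation). The stress-response genes that fell numbered 2 without RC siDux replicate 1 and 3 without RC siDux replicate 3, and the endoderm genes that rose 3 without RC control replicate 2 or 3 and 2 without RC siDux replicate 1 or 3.

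The lists of ribosomal proteins (median -0.24, adjusted p = 1.92e-06), ribosome biogenesis (median -0.12, adjusted p = 0.0135) and translation factors (median -0.14, adjusted p = 0.00643) passed downwards with 2 of 76, 4 of 65 and 3 of 30 members called lower (0, 1 and 5 list-wise), and these calls were lost (adjusted p = 0.661, 0.721 and 0.661 with an estimated correlation). Without RC control replicate 2 their medians were -0.03, -0.05 and -0.05. The members called lower numbered 17, 7 and 6 without RC control replicate 1 and 24, 8 and 5 without RC control replicate 3, and at most 0, 2 and 1 in edgeR without any one of the other 4 libraries (2 to 21 ribosomal proteins at an unadjusted p under 0.05). Under ERCC scaling their medians turned to 0.11, 0.20 and 0.19 (-0.20, -0.11 and -0.12 relative to all genes). The other lists did not pass (adjusted p from 0.0779 to 0.982), with Dmrtb1 of the germline list (1.70 ± 0.20) and the histone gene Hist1h2bc (1.43 ± 0.24) rising and Lin28a falling (-0.50 ± 0.09). The germline median was -0.06 (0.35 with ERCC scaling) beside a mean of 0.11 and a test pointing up, and the pluripotency median was 0.01 beside a mean of -0.06 and a test pointing down. Without RC control replicate 2 these medians were 0.16 and 0.07, and the pluripotency one ran from -0.07 to 0.08 with libraries left out. Pou5f1 (-0.26 ± 0.13, adjusted p = 0.2) and Nanog (0.32 ± 0.17, adjusted p = 0.229) did not pass, and neither did Ncl (-0.38 ± 0.12, adjusted p = 0.0589). Ncl passed with DESeq2, with no filter, with the replicate block and without RC control replicate 1 (-0.46) or RC control replicate 3 (-0.45).

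MERVL-int (-0.23 ± 0.22, adjusted p = 0.635) and MT2_Mm (-0.39 ± 0.17, adjusted p = 0.311) did not pass with siDux under RC ASO, nor did their group (adjusted p = 0.332). RLTR45-int rose by 1.09 ± 0.17 (adjusted p = 0.00565), a call lost in a fit on the 6 libraries compared, and SSU-rRNA_Hsa rose by 0.62 ± 0.11 (adjusted p = 0.0114), a call lost in that fit, with repeats scaled by their own totals and without RC siDux replicate 3 (0.56). MLT1G3, chosen after its values were seen, fell by 0.97 ± 0.20, a call lost in that fit and without RC control replicate 2 (-0.78), RC siDux replicate 1 (-0.88) or RC siDux replicate 3 (-0.93). Without RC control replicate 2, 4 subfamilies rose, and without RC siDux replicate 3, 1 did, while 5 fell without RC control replicate 3. The L1Md (median 0.58, adjusted p = 0.000941) and older L1 groups (median 0.19, adjusted p = 0.0203) passed upwards, a call lost (adjusted p = 0.877 and 0.949 with an estimated correlation). Over all genes 895 rose and 661 fell, 342 and 44 of them at least 2-fold. Leaving out RC siDux replicate 1 gave 593 and 221, RC siDux replicate 3 gave 406 and 154, RC control replicate 3 gave 1093 lower, a fit on the 6 libraries compared gave 201 and 41 (ending the calls of Snrpe, Sars, Nars and Lin28a), and DESeq2 gave 1002 lower. With the replicate block 1331 rose and 1126 fell, and 21 repeats rose and 4 fell. With ERCC scaling the median of all genes was at 0.31 and 187 genes were higher and 10 lower, the 2-cell-like list stood at -2.03 and the p53 list at 0.49 relative to all genes, and the calls of Ephx1, Bst2, Col4a1, Snrpe, Sars, Nars and Lin28a ended.

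The fourth comparison asked what siDux does on top of the LINE1 ASO, with LINE1 siDux set against LINE1 control. The 2-cell-like genes fell, 20 of 34 (31 fell and 1 rose list-wise), with a median log2 change of -1.60. Zscan4c fell from 18.7 ± 1.63 to 5.81 ± 0.587 CPM (log2 change -1.69 ± 0.23, adjusted p = 0.00352, n = 3 in each group). Zscan4a fell by 1.96 ± 0.26, Zscan4d by 1.79 ± 0.25, Zscan4f by 1.95 ± 0.25, Tcstv3 by 1.82 ± 0.21 (adjusted p = 0.0021), Gm12794 by 1.83 ± 0.23 and B020031M17Rik by 1.81 ± 0.28. The list passed as a set (adjusted p = 1.48e-68) and did so too with an estimated correlation (adjusted p = 0.0411). MERVL-int fell from 1993 ± 161 to 812 ± 137 CPM (log2 change -1.30 ± 0.22, adjusted p = 0.00591), a call lost without LINE1 siDux replicate 2 (-1.19), and MT2_Mm fell by 1.16 ± 0.17 (adjusted p = 0.002). These were the only subfamilies that passed in this comparison, and their group passed (adjusted p = 1.36e-20, and adjusted p = 0.00399 with an estimated correlation). Msln, which encodes the surface protein mesothelin, rose by 1.38 ± 0.19 and the endothelial receptor gene Robo4 by 1.17 ± 0.17.

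In this comparison 3 of 31 p53 targets rose (17 list-wise, median 0.37) and the list passed as a set (adjusted p = 7.91e-12), a call lost (adjusted p = 0.203 with an estimated correlation). The stress-response (median -0.32, adjusted p = 1.77e-08) and S-phase lists (median -0.07, adjusted p = 0.0154) passed downwards. The trophoblast (median 0.22, adjusted p = 0.000995), histone (0.49, 0.00194), mesoderm (0.37, 0.00211), germline (0.12, 0.00716) and endoderm lists (0.13, 0.0286) passed upwards, the germline one with a median of -0.00 under ERCC scaling (0.12 relative to all genes). These calls were lost (adjusted p from 0.203 to 0.606 with an estimated correlation). Of these 7 lists edgeR called 1 histone gene higher and 0 other members. At an unadjusted p under 0.05 there were 13 stress-response and 3 S-phase genes lower, and 6 trophoblast, 4 mesoderm, 6 germline and 4 endoderm genes higher. Medians moved by over 1.5 times without LINE1 control replicate 1 (S-phase -0.04, endoderm 0.25, germline 0.23, mesoderm 0.59), LINE1 control replicate 3 (S-phase -0.12, endoderm 0.20, germline 0.04, histones 0.31), LINE1 siDux replicate 2 (mesoderm 0.60, histones 0.25) and LINE1 siDux replicate 3 (S-phase -0.02, germline 0.20). Over all genes 80 rose and 45 fell, 21 and 28 of them at least 2-fold. Each library left out lowered both counts by over 1.5 times, to 15, 9 and 4 higher and 17, 16 and 11 lower genes without LINE1 control replicates 1, 2 and 3. The counts were 34, 9 and 8 higher and 16, 9 and 16 lower without LINE1 siDux replicates 1, 2 and 3. The 2-cell-like genes that fell numbered 13 and 9 without LINE1 control replicates 1 and 3 and 11 and 8 without LINE1 siDux replicates 1 and 2. DESeq2 called 221 genes higher and 101 lower. With the replicate block 305 were higher and 141 lower. With ERCC scaling the median of all genes was at -0.12, edgeR called 0 genes higher and 6 lower (134 at an unadjusted p under 0.05), the 2-cell-like list stood at -1.62 relative to all genes, and the calls of Zscan4c, Msln and Robo4 ended.

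The fifth comparison repeated the contrast of ASOs under siDux, in libraries that the first one did not use. The 2-cell-like genes rose in LINE1 siDux against RC siDux, 23 of 34 (31 list-wise), with a median log2 change of 2.92, a 7.55-fold rise. Zscan4c rose from 0.230 ± 0.260 to 5.81 ± 0.587 CPM (log2 change 4.48 ± 0.41, adjusted p = 2.57e-05, n = 3 in each group), Zscan4d by 4.91 ± 0.46, Tcstv1 by 5.46 ± 0.52, Tcstv3 by 3.45 ± 0.33 and Gm8300 by 2.51 ± 0.34. The starting level was 0, 2 and 8 counts for Zscan4c and 1, 0 and 6 for Zscan4d. The list passed as a set (adjusted p = 2.4e-63) and did so too with an estimated correlation (adjusted p = 0.0411). Arhgef33 rose by 2.61 ± 0.24, Cubn by 1.54 ± 0.23, Taf7l by 1.15 ± 0.20 and Trp53inp1 by 0.74 ± 0.12, and Hmmr fell by 0.56 ± 0.08. Dux (1.57 ± 0.63, adjusted p = 0.171), Pou5f1 (-0.45 ± 0.13, adjusted p = 0.0632), Nanog (-0.33 ± 0.17, adjusted p = 0.274), Cdkn1a (0.33 ± 0.20, adjusted p = 0.36) and Ncl (-0.19 ± 0.12, adjusted p = 0.408) did not pass. Pou5f1 passed with DESeq2, with no filter, with the replicate block and in a fit on the 6 libraries compared (log2 changes from -0.45 to -0.44).

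Ribosomal protein genes (median -0.26, adjusted p = 2.12e-14), ribosome biogenesis (-0.17, 1.86e-07), cholesterol (-0.27, 4.58e-07), translation (-0.16, 5.34e-06), pluripotency (-0.26, 6.78e-06), stress-response (-0.19, 0.000467) and interferon genes (-0.23, 0.00524) passed downwards in the same contrast, and germline genes upwards (0.22, 0.00643). In edgeR the lower members numbered 1 of 76 ribosomal proteins (32 at an unadjusted p under 0.05), 0 of 65 in ribosome biogenesis (18), 2 of 22 in cholesterol (12), 1 of 30 in translation (12), 0 of 26 in pluripotency (10), 3 of 29 in stress response (11) and 0 of 26 interferon genes (6), and 1 of 27 germline genes was higher. Without LINE1 siDux replicate 3, 4 ribosomal proteins were lower. Among p53 targets 5 of 31 rose (11 list-wise), with a median of 0.22 that turned to -0.03 with ERCC scaling (0.19 relative to all genes), and the list passed (adjusted p = 3.2e-05). The calls of all 9 lists were lost (adjusted p from 0.157 to 0.518 with an estimated correlation). The p53 targets that rose numbered 1 and 1 without RC siDux replicates 1 and 2 and 3, 3 and 3 without LINE1 siDux replicates 1, 2 and 3. Their median was 0.36 without RC siDux replicate 3 and 0.11 without LINE1 siDux replicate 3. The stress-response median was -0.34 and -0.31 without RC siDux replicate 1 and LINE1 siDux replicate 1, the interferon one -0.15 without RC siDux replicate 3 and the germline one 0.11 without LINE1 siDux replicate 1. The remaining lists did not pass. The retroviral repeat MMERGLN-int rose by 1.02 ± 0.12 (adjusted p = 8.6e-05), RLTR1B by 0.89 ± 0.17, RLTR10C by 0.86 ± 0.18, MMERVK10C-int by 0.77 ± 0.17 and MLT1G, chosen after its values were seen, by 1.29 ± 0.26, and SSU-rRNA_Hsa fell by 0.58 ± 0.11. Of these calls only that of MMERGLN-int held whichever library was left out. The subfamilies that rose numbered 3, 1 and 2 without RC siDux replicates 1, 2 and 3 and 1 and 1 without LINE1 siDux replicates 1 and 2, and 2 fell without LINE1 siDux replicate 3. MERVL-int (0.84 ± 0.22, adjusted p = 0.0969) and MT2_Mm (0.73 ± 0.17, adjusted p = 0.0585) did not pass singly, but both did with DESeq2, with no filter, with the replicate block and in a fit on the 6 libraries compared (0.81 to 0.85 and 0.72 to 0.75). For L1Md (median 0.06), ETn and MusD (0.10), B1 (0.03) and B2 and B3 (0.02) the medians were positive while the test pointed down, and none passed. The MERVL group passed (median 0.73, adjusted p = 0.00691), as did older L1 (0.21, 0.00245) and IAP (0.26, 0.0232), a call lost (adjusted p = 0.661, 0.949 and 0.949 with an estimated correlation).

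Over all genes 340 rose and 110 fell under siDux, 172 and 7 of them at least 2-fold. Leaving out RC siDux replicates 1 and 2 gave 94 and 96 higher and 17 and 11 lower genes, leaving out LINE1 siDux replicates 1 and 2 gave 117 and 167 higher and 11 and 18 lower. DESeq2 gave 564 higher and 336 lower genes, and a fit on the 6 libraries compared gave 348 lower. With ERCC scaling the median of all genes was at -0.22, 38 genes were higher and 3 lower, the 2-cell-like list stood at 2.97 and the ribosomal protein list at -0.28 relative to all genes, and the calls of Cubn, Taf7l, Trp53inp1 and Hmmr ended.

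Across genes, the LINE1 ASO changes with and without siDux were correlated (Pearson r = 0.719, Spearman correlation = 0.714), although the comparisons share no library. Of 2798 genes called under siControl, such as Arhgef33 and Zscan4d, 2756 (98.5%) had the same sign under siDux and 377 (13.5%) also passed there in the same direction. Of these 294 were higher and 83 lower, where independent lists would share 32 and 11. Over the genes called under siControl the median ratio of the log2 change under siDux to that under siControl was 0.562, lowered by choosing genes on its denominator. Over the 450 genes called under siDux the median of the inverse ratio was 1.02, also lowered by choosing genes on its denominator. Between the siDux comparisons, 1538 of the 1556 genes called under RC ASO (98.8%) had the same sign under LINE1 ASO, as did 73.7% of all genes, and 105 also passed there. The median ratio of the change under LINE1 ASO to that under RC ASO was 0.490 over these genes, lowered by the same choice, and the median of the inverse ratio was 1.41 over the 125 genes called under LINE1 ASO.

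**Figure D5:**
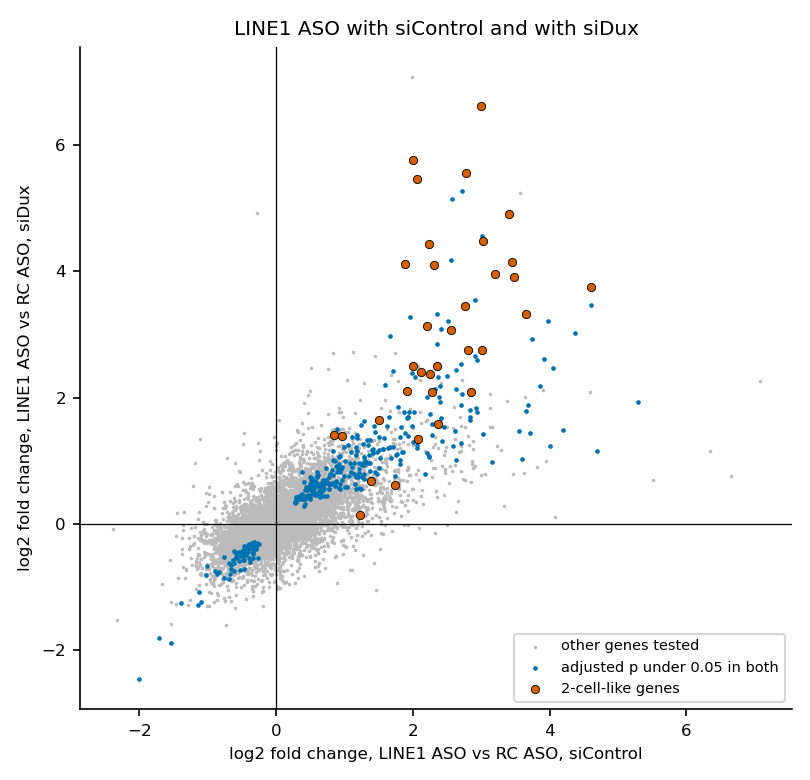
Log2 fold change of each gene tested for LINE1 ASO against RC ASO under siControl (horizontal axis) and under siDux (vertical axis). Blue points are genes with an adjusted p under 0.05 in both, orange points the 2-cell-like genes and grey points other genes, and across all genes Pearson r is 0.719.

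Whether the LINE1 ASO effect differs with siDux was tested as an interaction. The 2-cell-like genes Zscan4c (log2 difference 1.45 ± 0.58, adjusted p = 0.981) and Tcstv1 (3.41 ± 0.69, adjusted p = 0.268) did not pass. Neither did Zfp750 (-1.08 ± 0.29, adjusted p = 0.763), Dmrtb1 (-0.93 ± 0.27, adjusted p = 0.981), Mdm2 (-0.61 ± 0.20, adjusted p = 0.981) or Dux (-0.79 ± 0.96, adjusted p = 0.981). Over all genes edgeR called 0 (smallest adjusted p = 0.0957), with 491 genes at an unadjusted p under 0.05, while DESeq2 called 1 higher and 8 lower, Tcstv1 among them (log2 difference 3.49). For repeats both tools called 0, with 25 at an unadjusted p under 0.05 in edgeR. As sets, the 2-cell-like list passed upwards (median 0.43, adjusted p = 0.00141, -0.01 with ERCC scaling and 0.42 relative to all genes). Few counts of Zscan4c, Zscan4d and Tcstv1 in RC siDux leave this direction uncertain. Ribosomal proteins passed upwards too (median 0.23, adjusted p = 1.98e-08, -0.26 with ERCC scaling and 0.17 relative to all genes). The p53 targets (median -0.22, adjusted p = 6.69e-07) and MERVL group (-0.77, 2.46e-05) passed downwards. These calls were lost (adjusted p = 0.65, 0.605, 0.305 and 0.16 with an estimated correlation). The ribosomal protein median was -0.01 without RC control replicate 2. The 2-cell-like median was 0.27 without RC control replicate 1 and 0.18 and 0.72 without RC siDux replicates 2 and 3, and the p53 median -0.08 without RC siDux replicate 3.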

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

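Of the tests in this part, those of the gene totals under LINE1 ASO and RC ASO, of the bounds on the L1Md changes, of the ribosomal protein median under siDux, of the general rise of repeat counts and of the spread between replicates were chosen only after the result was seen, as was the bound on how well lists matched on gene length must match.

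Results were flagged where the LINE1 ASO effect on a list or repeat group differed with siDux in the interaction test. The 2-cell-like list, with few counts of some members in RC siDux, had a median log2 difference of 0.43 (adjusted p = 0.00141, and 0.65 with an estimated correlation). Ribosomal proteins had 0.23 (adjusted p = 1.98e-08, and 0.605 with an estimated correlation), ribosome biogenesis 0.12 (0.000158 and 0.605), translation factors 0.13 (0.000421 and 0.575), cholesterol genes 0.14 (0.00379 and 0.467), p53 targets -0.22 (6.69e-07 and 0.305) and mesoderm markers -0.30 (0.0432 and 0.467). Among repeats, MERVL had -0.77 (2.46e-05 and 0.16), L1Md -0.47 (0.0125 and 0.949) and ETn and MusD -0.31 (0.0391 and 0.805). None of these passed with an estimated correlation. With the replicate block the mesoderm call was lost (adjusted p = 0.056) and the MaLR repeats gained one (0.0488, and 0.0983 without the block). Without RC ASO + siControl replicate 2 the medians were -0.01 for ribosomal proteins, 0.06 for ribosome biogenesis and 0.04 for translation factors. With each library left out in turn, medians ran from 0.18 to 0.72 for 2-cell-like genes, 0.05 to 0.21 for cholesterol genes, -0.28 to -0.08 for p53 targets and -0.54 to -0.16 for mesoderm markers. With ERCC scaling, the medians of 2-cell-like genes, ribosomal proteins, ribosome biogenesis, translation factors and cholesterol genes turned to -0.01, -0.26, -0.32, -0.34 and -0.30 (0.42, 0.17, 0.11, 0.09 and 0.13 relative to all genes). No single gene passed in edgeR's interaction test, with 491 at an unadjusted p under 0.05, and DESeq2 called 1 higher and 8 lower.

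The first pattern is that siDux changed 1556 genes under RC ASO, Mdm2 and Tcstv1 among them, and 125 under LINE1 ASO (with the replicate block 1331 and 1126 higher and lower against 305 and 141), although the interaction test did not show the difference. The tables argue against a single control library, since 1240 genes were called without RC ASO + siControl replicate 2. They argue against fewer reads with LINE1 ASO, since gene totals there were 1.65 times those under RC ASO on average, while the ratio of the counts after thinning (36.1, and 12.4 before) decides nothing, since thinning takes reads mainly from those libraries. They argue against control libraries apart from all others as the whole cause, since 98.8% of the genes moved the same way under LINE1 ASO (96.5 to 98.9 with libraries left out, and 73.7% over all genes). A smaller effect of siDux with LINE1 ASO stays open, since the interaction test called 0 genes in edgeR (491 at an unadjusted p under 0.05) and 1 higher and 8 lower in DESeq2, and the ratios of the effects are taken over genes chosen by their calls, and effects of the siDux oligonucleotides on other transcripts were not tested.

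The second pattern is the lower level of ribosomal protein genes, such as Rpl23a and Fau, with LINE1 ASO under siControl. For gene length and abundance, 0% of 10000 random lists matched on both had a median as low. Their median was -0.385 against -0.519 for the ribosomal proteins. They were less abundant (8.98 against 9.53 log2 CPM) and longer (2088 against 1770 bases), so neither cause can be told apart. For a single control library, 28 of 62 genes were called without RC ASO + siControl replicate 2, between the bounds set beforehand, and the median went from -0.52 to -0.26, so its part cannot be told apart either. Control libraries apart from all others stay undecided too. Under siDux, without them, the median was -0.256 (-0.307 to -0.198 with libraries left out). The list call was then lost with an estimated correlation (adjusted p = 0.467). A lower transcript level with LINE1 ASO stays open as a hypothesis.

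The third pattern is that L1Md RNA was not lower with LINE1 ASO under siControl. Without RC ASO + siControl replicate 2 the median log2 change was 0.33 (0.51 with it). The summed change had 95% bounds of -0.212 and 0.854. Under siDux, without RC control, L1Md was not lower either (median 0.06, -0.04 to 0.08), with no bounds computed. So a single control library cannot be told apart. Nor can a general rise of repeat counts. The L1Md median less that of all repeats was 0.313 but the L1Md sum over the other repeats had 95% bounds of -0.164 and 0.991. Nor can spread between replicates. The summed L1Md change of 0.50 had 95% bounds of 0.014 and 0.991 in edgeR (-0.0158 and 1.02 on the 10 residual degrees of freedom). With the replicate block, whose numbers do not pair these libraries by the rule, they were 0.22 and 0.79. Blocked translation or function without RNA loss, and reads of old or intronic copies the ASO does not reach, stay open and untested.

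Other splits of the 6 libraries into 3 and 3 are too few (10) for a share under 0.05. For LINE1 ASO under siControl 1 split, the real one, reached the 2798 genes called, and the highest other called 0. The same held for siNcl (1 split, 4759 genes, highest other 0), siDux under RC ASO (1 split, 1556 genes, 0), LINE1 ASO under siDux (1 split, 450 genes, 0) and the direct test of LINE1 control against RC siNcl (1 split, 2923 genes, 0). For siDux under LINE1 ASO 2 splits reached the 125 genes called, and the other one, which set LINE1 ASO + siControl replicates 1 and 2 with LINE1 ASO + siDux replicate 1 against the rest, called 147, which points to a structure of the samples beside the groups. In the siDux comparisons, where same-number libraries correlate, the real split parts 3 same-number pairs and that other split parts 1. For repeats 1 split reached the real count for LINE1 ASO under siControl (47, highest other 5), siNcl (60, 0), siDux under RC ASO (3, 0), LINE1 ASO under siDux (6, 0) and the direct test (4, 0), and 2 splits did for siDux under LINE1 ASO (2, highest other 5). For the interaction the real count was 0 in edgeR, which any split reaches (40 of 40 for genes, highest other 0, and 40 of 40 for repeats, highest other 15), so these splits decide nothing.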

How the results depend on the processing

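Of the tests in this part, ERCC scaling and thinning to equal depth were chosen only after the data were seen. In what follows A is LINE1 ASO against RC ASO under siControl, B siNcl against siControl, C siDux under RC ASO, D siDux under LINE1 ASO, E LINE1 ASO under siDux, F the interaction and G LINE1 control against RC siNcl, and pairs of numbers are features higher and lower. With RLE scaling all 197 results of named genes kept direction and call, where a gene counts anew in each comparison. ERCC scaling ended 83 calls among these 197 results and turned none. A fit on the compared groups only ended 25 and added 5 calls among 229 results of named genes and repeats. Leaving out single libraries ended 52 and added 9 among 1440 values, and DESeq2 added 6 among 233. No result reversed its direction past the threshold. With an estimated correlation 60 of 126 list results and 13 of 63 repeat group results no longer passed.

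Counts that moved by over 1.5 times, the cause not being tested, were these. ERCC scaling gave for genes A 278 and 2, B 563 and 68, C 187 and 10, D 0 and 6 (134 at an unadjusted p under 0.05 in edgeR), E 38 and 3, and G 106 and 19. The fit on compared groups only, with fewer libraries to estimate the spread from, gave A 364 and 32, B 1240 lower, C 201 and 41, D 50 higher and E 348 lower, and for repeats A 6 and 0 (132 at an unadjusted p under 0.05 in edgeR), B 10 and 1, C 0 and 0 (62 at an unadjusted p under 0.05), E 10 and 2 and G 2 higher. DESeq2 gave C 1002 lower, D 221 and 101, E 564 and 336 and F 1 and 8, and for repeats A 19 lower, B 20 lower, C 4 and 2, E 2 lower and G 3 higher. The strict filter gave D 23 lower, E 207 and 64 and for repeats G 2 higher, no filter gave F 1 lower and for repeats A 14 lower and E 8 and 2, thinning gave D 24 and 12 and E 70 lower, and own library sizes and TMM gave for repeats A 26 lower, B 34 lower, C 1 higher and G 3 higher.

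Over all groups the replicate numbers do not pair the libraries by the rule set beforehand, since 23 of 30 same-number pairs correlated above 0.1 (-0.00389 to 0.556), although in C and D each of 3 pairs did and 15 of 15 libraries correlated best with their own number, a hint from the data and not from the design. With the replicate block the counts that moved were C 1126 lower, D 305 and 141 and E 766 and 463, and for repeats A 106 and 23, B 109 and 28, C 21 and 4, E 11 and 2 and G 7 and 5. Among lists, 123 of 126 kept their call under it, while mesoderm in F (adjusted p = 0.056) and G2/M in G (0.0703) lost theirs and fibroblast markers in G (0.0424) gained one. Among repeat groups L1Md in A (0.00464) and MaLR in F (0.0488) gained a call under it. Of named genes in C and D, the block changed the call of Ncl in C alone.

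With each library left out in turn, genes ranged in A from 473 to 1774 higher and 113 to 1833 lower, in B 1843 to 2434 and 1487 to 2590, in C 406 to 927 and 154 to 1093, in D 4 to 34 and 9 to 17, in E 94 to 413 and 11 to 133, in F 0 to 0 and 0 to 1, and in G 819 to 1603 and 911 to 1610. Repeats ranged in A from 10 to 91 and 1 to 24, in B 19 to 65 and 5 to 24, in C 1 to 4 and 0 to 5, in D 1 to 2 lower, in E 1 to 6 and 0 to 2, and in G 0 to 1 and 1 to 1. The correlation of A with B ranged from 0.642 to 0.760, with 397 to 942 shared higher and 85 to 1232 shared lower genes. That of A with E ranged from 0.652 to 0.721, with 96.0% to 99.4% of one sign, 3.43% to 42.0% also called and a median ratio of 0.439 to 0.675. Depth limits genes with few counts, such as Dux, with at most 30 in any library.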
